A study of Mus musculus with 22 samples.

How the data were processed

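Gene expression was measured with 1-colour Affymetrix whole-transcript arrays in 22 samples of white fat from male C57BL/6J mice. Per the labels' protocols, the mice were bone marrow chimeras: the marrow was left 6 weeks to reconstitute, and a high-fat diet with 60% of calories from fat followed for 14 weeks. Epididymal fat (epiWAT) and inguinal subcutaneous fat (ingWAT) were taken out, frozen and kept cold until RNA was prepared with a lipid tissue kit. Biotin-labelled targets were made from 100 ng of total RNA. The marrow was wild type (WT), Gipr-/- (without the receptor of the incretin hormone GIP) or Gipr-/-S100a9-/-, called double-knockout marrow here. The recipients were WT for the first 2 kinds of marrow, per the labels' protocols; for double-knockout marrow the recipient is not given in the sources used here.

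The authors deposited a table of 21793 features with values on a log scale, taken here as log2 values that the submitters made from the arrays with Partek 6.6 among their tools. The values run from 1.92 to 19.9; neither the base nor the normalization is given in the sources used here, so each log2 difference rests on that reading. The role of Partek is not given either. Array medians lay between 6.11 and 6.54 and array means between 6.98 and 7.08. Arrays of a group correlated with r between 0.911 and 0.984, and there were 0 identical pairs. Array data carry no read depth; the number of arrays limits the precision. The platform annotation gave 1 gene symbol to 19341 features, several symbols to 0, and 2452 are unnamed here. Matched by gene identifier, all 19341 symbols were current. Of the 4 genes with 2 features each, the feature with the higher mean over the 22 arrays was kept, which left 19337 genes.

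The choices in this paragraph were made before the data were examined, except where said. Groups came from the labels: in epiWAT 4 arrays per kind of marrow, and in ingWAT 4 with WT, 3 with Gipr-/- and 3 with double-knockout marrow. Arrays are numbered within a group in accession order, which names them and pairs nothing. The labels do not say outright that each array is a separate mouse, so the p-values measure the spread between these samples. Each depot was fitted apart, its 3 groups in one fit, with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3. The 25% of genes with the lowest mean in the depot were left out, which left 14502 genes. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Contrasts between depots came from a fit of all 22 arrays in 6 groups. The fit was tested on simulated data, in which 200 of 14502 genes carried a known change of 1 to 4 log2 units in each of 10 simulations. Each simulated gene varied independently. The share recovered is given with each comparison. With so many changed genes the adjusted threshold is easier to reach, so these shares are too high where few genes change.

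Gene lists were fixed from general knowledge of fat tissue: thermogenic and beige adipocyte genes, mature adipocyte genes, lipogenesis, fatty acid oxidation, oxidative phosphorylation, insulin signalling, S100 family and alarmin receptors, neutrophil, monocyte and macrophage markers, lipid-associated macrophage genes, inflammatory cytokines and chemokines, type 2 immunity and eosinophils, interferon response, T and NK cell, B cell and plasma cell, mast cell and dendritic cell markers, MHC class II presentation, extracellular matrix and fibrosis, adipose progenitor and endothelial markers, lymph node stroma markers, skeletal muscle genes, epididymis epithelium genes, mesothelium markers, skin and gland epithelium markers, cell cycle, unfolded protein and integrated stress response, red blood cell genes, circadian clock genes, immediate early genes, and inguinal and epididymal depot developmental genes. They were tested with camera (preset correlation 0.01) against all other genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Lists with fewer than 5 tested members, which were lymph node stroma markers and red blood cell genes, were not tested, and the depot lists were tested only between depots, so 30 lists were tested within each depot. Beside the count of members past the threshold over all genes stands the count adjusted over the list alone. Camera with an estimated correlation and fry were alternatives. A list score is the mean over the list's genes of the log2 value minus the gene's mean; an exact permutation test of these scores was added after the data were seen. Lists of testis germ cell, hair follicle and liver secretory genes were also written after the data were seen.

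The genes named were chosen by rule. Gipr, S100a8 and S100a9 are named in every comparison. Among genes past the threshold, the 10 with the largest change in each direction are named, or the 5 with the smallest p where fewer than 5 passed. From each list that camera called, the 4 members with the smallest p may be named, and a set of focus genes is given by value. Between depots the 5 genes with the smallest p in each direction are named. Predicted genes, Riken clones and ribosomal, olfactory, vomeronasal, microRNA and snoRNA genes were counted and not named. Ucp1, Dio2, Tnf and Il6 fell among these dimmest genes and were not tested.

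Other settings chosen at the outset were no filter on dim genes, leaving out the lower 50% in place of the lowest 25%, eBayes without the trend or with robust estimation, array weights, quantile normalization, all features, all 22 arrays in one fit, and leaving out each array in turn. The sample titles carry number codes whose meaning is not given in the sources used here. In ingWAT the codes 64 to 75 and 87 to 92 stand apart and were used as a block, and samples of the depots whose codes differ by 15 were used as a random block. Added after the data were seen were fits without the arrays that held genes of another tissue, fits with the scores of those tissues as covariates, and the code block for the ingWAT lists. Likeness of comparisons that share arrays was set beside 100 simulations of unchanged groups. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.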

Results

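Whole-transcript arrays measured gene expression in 12 epididymal (epiWAT) and 10 inguinal (ingWAT) fat samples of male mice that carried transplanted bone marrow and ate a high-fat diet for 14 weeks. The marrow was WT, Gipr-/- or Gipr-/-S100a9-/- (double knockout). Gipr encodes the receptor of GIP, a gut hormone released after meals, and S100a9 encodes a calcium-binding alarmin subunit that pairs with the product of S100a8 and is abundant in neutrophils and monocytes. EpiWAT had 4 arrays per kind of marrow; ingWAT had 4 arrays with WT, 3 with Gipr-/- and 3 with double-knockout marrow. The adipocyte hormone genes were among the brightest features, with a mean log2 value over the 22 arrays of 19.1 for Adipoq (adiponectin) and 17.9 for Lep (leptin).

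None of the targeted genes passed the threshold between kinds of marrow. Whole fat consists mostly of tissue of the recipient, which bears less on S100a9, a gene of marrow-derived neutrophils and monocytes. Why S100a9 showed no clear fall was not tested. Where the probes lie relative to the deletions is not known, so these values check no label. In epiWAT the log2 value of Gipr was 5.07, 4.55, 4.81 and 4.71 with WT marrow, 5.21, 5.65, 5.51 and 5.14 with Gipr-/- marrow and 4.02, 6.1, 4.14 and 5.28 with double-knockout marrow; the Gipr-/- marrow arrays thus all lay above the WT marrow arrays. That of S100a9 in epiWAT was 5.89, 5.40, 4.95 and 5.24 with WT, 4.56, 4.77, 5.64 and 5.75 with Gipr-/- and 5.36, 5.07, 4.78 and 5.53 with double-knockout marrow. In ingWAT Gipr was 5.31, 4.36, 5.51 and 4.86 with WT, 4.66, 5.66 and 4.99 with Gipr-/- and 5.76, 4.92 and 5.56 with double-knockout marrow. There S100a9 was 5.12, 5.82, 6.45 and 5.23 with WT, 6.98, 5.35 and 6.16 with Gipr-/- and 6.35, 6.18 and 4.94 with double-knockout marrow. S100a8 in epiWAT averaged 5.42 ± 0.78 (SD, n = 4) with WT, 6.78 ± 1.01 (n = 4) with Gipr-/- and 5.26 ± 1.26 (n = 4) with double-knockout marrow. In ingWAT it averaged 5.60 ± 0.75 (SD, n = 4) with WT, 5.90 ± 1.16 (n = 3) with Gipr-/- and 4.90 ± 0.26 (n = 3) with double-knockout marrow. The largest differences in these 3 genes were in S100a8. They were 1.35 for Gipr-/- minus WT in epiWAT (SE 0.66, limma adjusted p = 0.705), -1.51 for double knockout minus Gipr-/- in epiWAT (SE 0.66, adjusted p = 0.437) and -1.0 for double knockout minus Gipr-/- in ingWAT (SE 0.56, adjusted p = 0.377). For Gipr-/- minus WT, Gipr differed by 0.59 in epiWAT (adjusted p = 0.806) and 0.09 in ingWAT (adjusted p = 0.946). S100a9 differed by -0.19 in epiWAT (adjusted p = 0.933) and 0.51 in ingWAT (adjusted p = 0.678). For double knockout minus Gipr-/-, Gipr differed by -0.49 in epiWAT (adjusted p = 0.674) and 0.31 in ingWAT (adjusted p = 0.749), and S100a9 by 0.00 (adjusted p = 0.998) and -0.34 (adjusted p = 0.798). For double knockout minus WT, the differences in epiWAT were 0.10 for Gipr, -0.16 for S100a8 and -0.18 for S100a9 (adjusted p = 0.999 for each). In ingWAT they were 0.40 (adjusted p = 0.697), -0.70 (adjusted p = 0.618) and 0.17 (adjusted p = 0.921). These genes sat low on the array, with a mean log2 value over the 22 arrays of 5.08 for Gipr, 5.67 for S100a8 and 5.52 for S100a9.

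**Figure D1:**
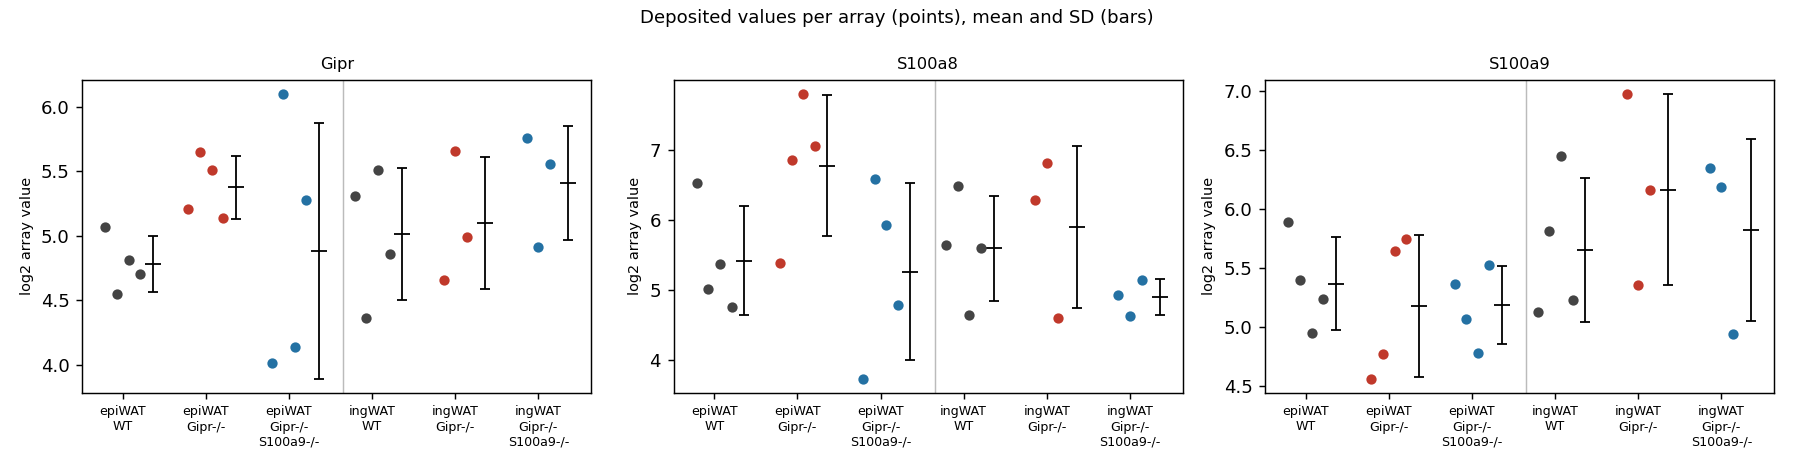
Log2 array value (y axis) of Gipr, S100a8 and S100a9 for each array (points) in the 6 groups of depot and marrow (x axis); bars give the group mean and SD. The groups overlap in most panels, and the Gipr-/- epiWAT arrays range from 5.39 to 7.80 for S100a8.

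How epiWAT differs when the marrow lacks the GIP receptor was seen in lists of genes and in no single gene. Camera called the lipid-associated macrophage list higher, and the lipogenesis and insulin signalling lists lower, with Gipr-/- than with WT marrow. These calls were lost with an estimated correlation (adjusted p = 0.434, 0.506 and 0.434 with an estimated correlation). The lipid-associated macrophage list rose as a group, with a median log2 difference of 1.10 over 17 tested members, 16 of them positive (camera adjusted p = 2.67e-10; adjusted p = 0.434 with an estimated correlation). Its score was 1.33 ± 0.46 (SD, n = 4) against 0.01 ± 0.71 (n = 4). An exact two-sided permutation test gave p = 0.0571 (0.312 adjusted over the 30 lists tested with camera). Gpnmb, a glycoprotein of macrophages in obese fat, differed by 3.33 and Atp6v0d2, a subunit of the lysosomal proton pump, by 4.27. Trem2, a lipid-sensing receptor, differed by 1.79 and the tetraspanin Cd9 by 0.93. For these 4 genes all 4 Gipr-/- arrays lay above all 4 WT arrays. They were picked by small p in this same comparison, so the separation is no separate support. Of the list, 7 members passed when adjusted over the list alone and 0 over all genes. The general macrophage list had a median of 0.30 and was not called (camera adjusted p = 0.0636). Adgre1 (F4/80) was at 0.78 and Itgax (CD11c) at 1.14.

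The lipogenesis list fell (median -0.57, 14 of 17 members negative, camera adjusted p = 0.000168; adjusted p = 0.506 with an estimated correlation). It includes Fasn, the fatty acid synthase (-1.13), Gpam, which starts glycerolipid synthesis (-1.15), and Mlxipl, the carbohydrate-responsive factor ChREBP (-1.30), and 0 members passed when adjusted over the list alone. The insulin signalling list fell too (median -0.53, 16 of 18 negative, camera adjusted p = 0.000168; adjusted p = 0.434 with an estimated correlation). It was led by Irs1, the main insulin receptor substrate of fat cells (-1.84, SE 0.30), Gys1 (-1.08), Akt2 (-1.05) and Insr (-0.58). These 4, again picked by small p in this comparison, were lower in each Gipr-/- array than in any WT array. Of the list, 2 members passed when adjusted over the list alone. Mature adipocyte genes had a median of -0.35 (13 of 17 negative, camera adjusted p = 0.0061; adjusted p = 0.773 with an estimated correlation). Pck1 was at -2.29 and Cebpa at -1.47, while Adipoq was at -0.09 and Lep at 0.59. For this list 1 member passed when adjusted over the list alone, and the call was lost without WT 4 or Gipr-/- 1 (adjusted p up to 0.0601). B cell and plasma cell genes rose (median 0.81, 9 of 10 positive, camera adjusted p = 0.000168; adjusted p = 0.482 with an estimated correlation), with Cd22 at 1.86. So did cell cycle genes (median 0.33, camera adjusted p = 0.00112; adjusted p = 0.485 with an estimated correlation), with the kinetochore motor Cenpe at 1.59. Testis germ cell genes scored 6.74 in Gipr-/- 1, 3.02 in WT 2 and -0.99 to 1.62 in the other epiWAT arrays. Immediate early genes rose as well (median 0.49, camera adjusted p = 0.00126; adjusted p = 0.482 with an estimated correlation), with Junb at 0.95. The immediate early call was lost without Gipr-/- 3 (adjusted p = 0.0563). The interferon response list fell (median -0.49, 16 of 18 negative, camera adjusted p = 0.0061; adjusted p = 0.773 with an estimated correlation), with Irf7 at -1.32. This call was lost without WT 1, WT 4 or Gipr-/- 1 (adjusted p up to 0.281). Mesothelium markers fell (median -0.63, camera adjusted p = 0.0302; adjusted p = 0.71 with an estimated correlation), with Upk3b at -1.88. This call was lost without any one of WT 2, 3 and 4 and Gipr-/- 1 and 3 (adjusted p up to 0.341). Genes of skeletal muscle rose (median 0.57, camera adjusted p = 0.0041; adjusted p = 0.434 with an estimated correlation), with Ckm at 1.33. Genes of skin and gland epithelium rose too (median 0.33, camera adjusted p = 0.021; adjusted p = 0.735 with an estimated correlation), with Cldn4 at 2.16. The skin call was lost without any one of WT 1, 3 and 4 and Gipr-/- 1 and 2 (adjusted p up to 0.213). Epididymis genes, whose score is 1.06 ± 1.72 (SD, n = 4) with WT and -0.27 ± 0.70 (n = 4) with Gipr-/- marrow, were not called.

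No single gene passed in this comparison. Limma called 0 of 14502 genes (lowest adjusted p = 0.131), with 1052 at an unadjusted p under 0.05, 484 higher and 568 lower. The smallest p-values among higher genes belonged to Cdh19, a cadherin of glial cells (2.26, SE 0.31), the myosin Myo1e (1.30), the kinetochore gene Spc25 (1.47), Purb (0.98) and the B cell gene Cd72 (1.58). Among lower genes they belonged to Irs1, Rhbdl1 (-1.57), the glycogen phosphorylase Pygb (-1.43), Nnat (-2.12) and G0s2, an inhibitor of adipose triglyceride lipase (-3.21, SE 0.56, adjusted p = 0.219). The WT and Gipr-/- values did not overlap for 731 genes, 5.04% of those tested, where chance gives 2.86%. This chance share, here and below, is an average, and genes that vary together can carry a single split far from it. Array weights called 26 genes, all features together 6, leaving out Gipr-/- 1 called 1, and the epididymis score as a covariate called 16. In simulations with 200 changed genes, 21% of genes changed by 1 log2 unit and 75% of those changed by 2 were recovered. With few changed genes the share would be lower.

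Adding the loss of S100a9 to the Gipr-/- marrow went with lower macrophage genes in epiWAT. The lipid-associated macrophage list fell (median -1.51, 16 of 17 members negative, camera adjusted p = 5.69e-12; adjusted p = 0.808 with an estimated correlation), with a score of -0.37 ± 0.83 (SD, n = 4) against 1.33 ± 0.46 (n = 4). The exact permutation p was 0.0286, the smallest that 4 against 4 arrays allow (0.429 adjusted over the 30 lists). All 4 double-knockout arrays lay below all 4 Gipr-/- arrays for Gpnmb (-3.62), Atp6v0d2 (-4.25), Trem2 (-2.02) and the lysosomal protease Ctss (-2.84). These 4 were picked by small p in this comparison, so their separation is no separate support. Over the list, 13 members passed when adjusted over the list alone, with 0 over all genes. General macrophage markers fell (median -0.74, 17 of 17 negative, camera adjusted p = 1.48e-05; adjusted p = 0.808 with an estimated correlation), with 3 members past the threshold when adjusted over the list alone. Adgre1 was at -1.82 and the mannose receptor Mrc1 at -1.79. Itgax was at -1.47 and the monocyte attractant Ccl2 at -1.41. Beside these lists, epididymis epithelium genes rose (median 3.68 over 9 members, camera adjusted p = 0.00665; adjusted p = 0.808 with an estimated correlation). Their score was 2.02 ± 2.46 (SD, n = 4) against -0.27 ± 0.70 (n = 4) and 5.51 in double knockout 1 alone. Gpx5, a secreted epididymal peroxidase, was at 6.65, and the call was lost without that array (adjusted p = 0.157).

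B cell and plasma cell genes fell (median -1.02, 10 of 10 negative, camera adjusted p = 9.95e-05; adjusted p = 0.808 with an estimated correlation), with Cd22 at -1.92. Cell cycle genes fell (median -0.49, camera adjusted p = 0.00361; adjusted p = 0.808 with an estimated correlation), with Tpx2 at -1.10, and this call was lost without Gipr-/- 1 (adjusted p = 0.0676), the array with the testis germ cell score of 6.74. The extracellular matrix list fell (median -0.65, 19 of 23 negative, camera adjusted p = 0.000165; adjusted p = 0.853 with an estimated correlation). Periostin (Postn) was at -1.52 and thrombospondin (Thbs1) at -2.10, and the call was lost without double knockout 1 (adjusted p = 0.0965). Immediate early genes fell (median -0.31, camera adjusted p = 0.0303; adjusted p = 0.808 with an estimated correlation), with Atf3 at -1.81. That call was lost without Gipr-/- 3 or double knockout 3 (adjusted p up to 0.272). Interferon response genes rose (median 0.33, camera adjusted p = 0.0368; adjusted p = 0.853 with an estimated correlation), with Irf7 at 1.31. Lipogenesis genes rose (median 0.50, camera adjusted p = 0.0446; adjusted p = 0.853 with an estimated correlation), with Gpam at 1.12. The interferon call was lost without Gipr-/- 1 or double knockout 2 or 4 (adjusted p up to 0.480), and the lipogenesis call without any one of WT 1, Gipr-/- 1 and 2 and double knockout 2 and 4 (adjusted p up to 0.417).

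For single genes limma called 0 of 14502 (lowest adjusted p = 0.143), with 1555 at an unadjusted p under 0.05, 765 higher and 790 lower. With all 22 arrays in one fit 1 gene passed. The smallest p-values belonged to Irs1 (2.00, SE 0.30), the Ras-related gene Rasd1 (3.76), G0s2 (3.08), Phb2 (0.83) and Bckdk (1.23) among higher genes. Among lower genes they belonged to Myo1e (-1.52), Ctss, Tnfrsf12a (-1.98), the cholesteryl ester hydrolase Nceh1 (-2.30) and Pde7a (-1.62). The choice by small p makes separate groups likely, and the double-knockout and Gipr-/- values of all of these did not overlap. Such genes numbered 877, or 6.05%, where chance gives 2.86%. Simulations recovered 18.6% of genes changed by 1 log2 unit and 72% of those changed by 2.

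Against WT marrow, double-knockout marrow went with lower adipocyte, macrophage and matrix lists in epiWAT, by calls that all depend on 1 array and are lost with an estimated correlation (adjusted p = 0.952 with an estimated correlation). No gene passed the threshold (limma 0 of 14502, lowest adjusted p = 0.999, 444 at an unadjusted p under 0.05, 209 higher and 235 lower). Mature adipocyte genes (median -0.49, 17 of 17 negative, camera adjusted p = 0.000231), macrophage markers (median -0.49, 16 of 17 negative, camera adjusted p = 0.000231) and extracellular matrix genes (median -0.62, 21 of 23 negative, camera adjusted p = 0.000231) fell. These 3 had an adjusted p = 0.952 with an estimated correlation. Lpl was at -0.54, Mrc1 at -1.23 and Col3a1 at -0.76. Insulin signalling (median -0.26, camera adjusted p = 0.0423), fatty acid oxidation (median -0.26, camera adjusted p = 0.0423) and lipid-associated macrophage genes (median -0.29, camera adjusted p = 0.0457) fell. Again each had an adjusted p = 0.952 with an estimated correlation. Genes of skin and gland epithelium (median 0.61, camera adjusted p = 0.0457), skeletal muscle (median 0.36, camera adjusted p = 0.0493) and epididymis (median 0.97, camera adjusted p = 0.0496) rose. These too had an adjusted p = 0.952 with an estimated correlation. Of the 9 lists, 0 members passed when adjusted over the list alone. All 9 calls were lost without double knockout 1, which left 1 other list called (adjusted p of matrix and adipocyte genes up to 0.631 and of macrophage markers up to 0.529). The 6 other lists were each lost without at least 3 further arrays as well. Insulin signalling was lost without WT 1 or 3 or double knockout 3 (adjusted p up to 0.529), and fatty acid oxidation without WT 1, 3 or 4 or double knockout 3 (adjusted p up to 0.957). Lipid-associated macrophage genes were lost without WT 1 or 3, Gipr-/- 1 or 2 or double knockout 4 (adjusted p up to 0.890), and skin genes without WT 1, 3 or 4, Gipr-/- 1 or 2 or double knockout 3 (adjusted p up to 0.939). Muscle genes were lost without WT 1, 2 or 3, Gipr-/- 1 or double knockout 2 or 4 (adjusted p up to 0.631), and epididymis genes without WT 3 or 4 or any Gipr-/- array (adjusted p up to 0.860). Camera's direction turned for 3 lists: epididymis genes without double knockout 1 (adjusted p = 0.860), and fatty acid oxidation (adjusted p = 0.837) and skin genes (adjusted p = 0.988) without the 4 arrays with a positive first component. The count was 4 without WT 1, 3 without WT 3 and 5 without Gipr-/- 1. Genes with the smallest p were Zfp395 (0.99), the polarity gene Scrib (0.97) and Slc25a38 (0.76) among higher and the histone demethylase Kdm2a (-0.89), Pus10 (-0.88) and Ints13 (-1.12) among lower genes. The groups did not overlap for 337 genes, 2.32% against 2.86% by chance. Simulations recovered 25% of genes changed by 1 log2 unit and 71.8% of those changed by 2.

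**Figure D2:**
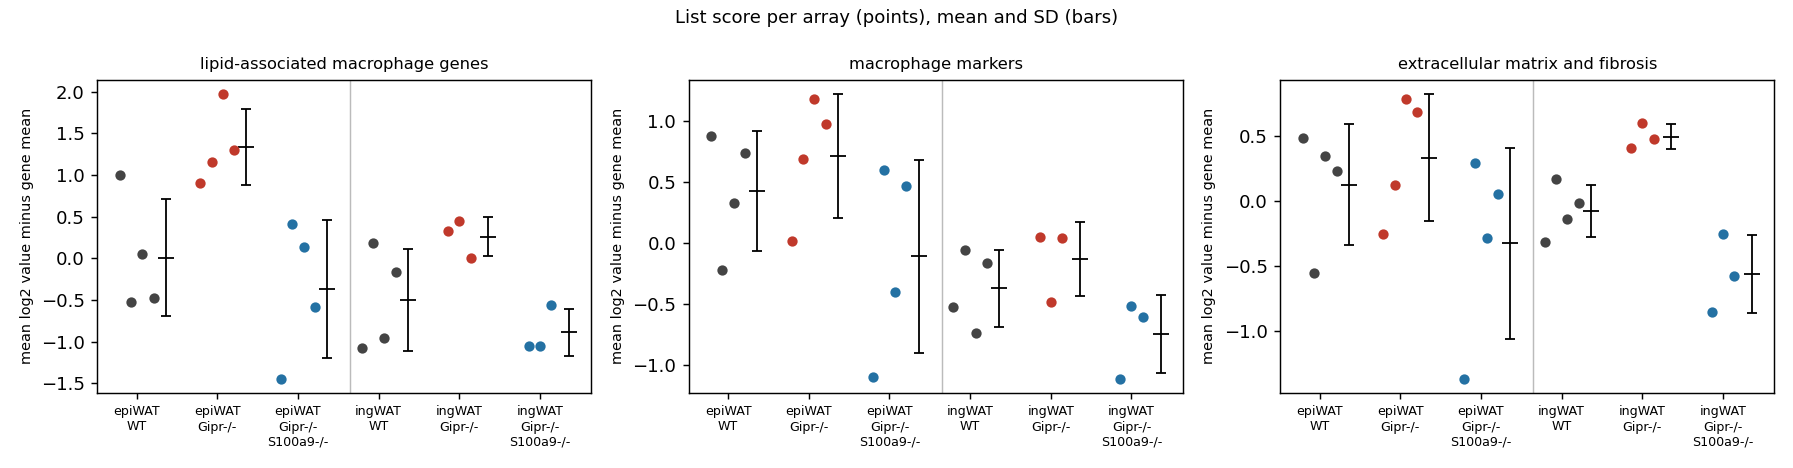
List score per array (points; y axis, mean log2 value minus the gene's mean over the 22 arrays) for lipid-associated macrophage genes, macrophage markers and extracellular matrix genes in the 6 groups (x axis); bars give the group mean and SD. In epiWAT the lipid-associated macrophage scores of the Gipr-/- arrays run from 0.91 to 1.97 and those of the double-knockout arrays from -1.44 to 0.41.

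In ingWAT, a small set of genes differed between Gipr-/- and WT marrow, most of them higher with Gipr-/- marrow. The 34 genes past the threshold were 30 higher and 4 lower than with WT marrow (limma; 2180 at an unadjusted p under 0.05, 1441 higher and 739 lower). The oxytocin receptor gene Oxtr was higher by 4.75 (SE 0.76, adjusted p = 0.0307), the proteoglycan gene Srgn by 2.77 (SE 0.30, adjusted p = 0.012) and the matricellular gene Ccn2 (CTGF) by 2.34. Its relative Ccn3 was higher by 2.09, the serine protease Prss23 by 2.12, the metalloprotease Adam12 by 2.09 and the microfibril gene Mfap5 by 1.99. Hspa5, the main chaperone of the endoplasmic reticulum, was higher by 1.52 (adjusted p = 0.0307), and Fam122b, Adap2 and Dcbld2 were also among the 10 largest. Marcks (-1.57), the phosphatase activator Ptpa (-2.00), Prrc2a (-1.76) and Zfp703 (-1.71) were lower. All of these named genes had Gipr-/- and WT values that did not overlap, which their choice by this same test makes likely. In all, 2231 genes did not overlap, 15.4% where chance gives 5.71% on average. Other splits of the arrays, counted below by genes past the threshold, do not exclude chance for this comparison. The count of 34 depended on single arrays. It was 0 without WT 1, Gipr-/- 1 or Gipr-/- 2, 1 without WT 3 or double knockout 3, 2 without WT 2, 87 without WT 4 and 274 without double knockout 2. It was also 0 with the title code groups as a block (1724 at an unadjusted p under 0.05), 1 without the trend, 3 after quantile normalization, 99 with all 22 arrays, 133 with robust estimation, 148 without the lower 50% of genes and 401 with array weights. Simulations recovered 17% of genes changed by 1 log2 unit and 80% of those changed by 2.

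Among the lists, extracellular matrix genes rose (median 0.46, 17 of 23 positive, camera adjusted p = 0.00253; adjusted p = 0.764 with an estimated correlation), with 5 members past the threshold when adjusted over the list alone. Lox, which cross-links collagen, was at 1.15, Postn at 2.23 and Thbs1 at 2.59. Lipid-associated macrophage genes rose (median 0.64, 15 of 17 positive, camera adjusted p = 0.00206; adjusted p = 0.764 with an estimated correlation). Galectin-3 (Lgals3) was at 2.06, the lysosomal lipase Lipa at 1.18 and Plin2 at 1.02, and 3 members passed when adjusted over the list alone. Endothelial markers rose (median 0.48, 15 of 16 positive, camera adjusted p = 0.00656; adjusted p = 0.808 with an estimated correlation), with Sox17 at 2.20 and Flt1 at 1.26. This was lost without WT 2 or Gipr-/- 3 (adjusted p up to 0.0817), and 2 members passed when adjusted over the list alone. The stress response list rose (median 0.62, 11 of 15 positive, camera adjusted p = 0.0259; adjusted p = 0.68 with an estimated correlation). Hspa5 and 2 further members passed when adjusted over the list alone, and the call was lost without WT 4, Gipr-/- 1 or Gipr-/- 3 (adjusted p up to 0.110). The thermogenic list fell (median -0.85, 12 of 16 negative, camera adjusted p = 0.0067; adjusted p = 0.68 with an estimated correlation). Ppargc1a, a regulator of mitochondrial biogenesis, was at -2.22 (SE 0.54, adjusted p = 0.0856), Cox7a1 at -2.32 and the beige fat factor Ebf2 at -1.0, while Cidea was at -0.21. The call was lost without Gipr-/- 1 (adjusted p = 0.0886), and 1 member passed when adjusted over the list alone. Skeletal muscle genes moved with it (median -4.69, 19 of 19 negative, camera adjusted p = 3.15e-07; adjusted p = 0.808 with an estimated correlation). Their score was 0.47 ± 1.39 (SD, n = 3) against 4.53 ± 4.40 (n = 4) with WT marrow. Skin and gland epithelium genes fell (median -1.76, camera adjusted p = 0.00661; adjusted p = 0.918 with an estimated correlation) and were lost without WT 1, WT 2 or Gipr-/- 1 (adjusted p up to 0.137). Without Gipr-/- 1 the 7 lists became 4.

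By the count of genes in the main fit, inguinal fat differed most between double-knockout and Gipr-/- marrow. Limma called 505 genes, 121 higher and 384 lower with double-knockout marrow (2745 at an unadjusted p under 0.05). The order of this comparison and Gipr-/- against WT turned when double knockout 1 and 3 were left out, which leaves a single double-knockout array. Among the largest falls, Oxtr fell by 6.53 (SE 0.81, adjusted p = 0.00529), the choline transporter Slc5a7 by 5.96 and the lipase Lipf by 4.78. Thbs1 fell by 4.63 (SE 0.56, adjusted p = 0.00529), the complement gene C6 by 4.45 and Lbp, which binds endotoxin, by 3.37. Leptin (Lep) fell by 1.44 (SE 0.32, adjusted p = 0.0331) while Adipoq differed by -0.07 (adjusted p = 0.897). Among genes past the threshold, the largest rises included genes of lymphocytes and lymph node, and Rasd1 and G0s2. Rasd1 and G0s2 were also higher by value in epiWAT. The B cell chemokine Cxcl13 rose by 5.37 (SE 1.09, adjusted p = 0.0237) and the BAFF receptor Tnfrsf13c by 4.29. The T cell receptor gene Cd3g rose by 4.29, the adaptor Lat by 3.62, Lef1 by 3.51, Rasd1 by 4.36 and G0s2 by 4.22 (SE 0.90, adjusted p = 0.0284). Lymph node stroma genes, which include Cxcl13, scored 3.36 and 3.35 in double knockout 1 and 3, -0.70 in double knockout 2 and -1.19 to -0.46 in the other ingWAT arrays.

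B cell and plasma cell genes rose (median 2.97, 12 of 12 positive, camera adjusted p = 1.32e-08; adjusted p = 0.446 with an estimated correlation). T and NK cell genes rose (median 1.91, 17 of 20 positive, camera adjusted p = 3.55e-07; adjusted p = 0.446 with an estimated correlation), as did dendritic cell genes (median 1.44, camera adjusted p = 0.000161; adjusted p = 0.446 with an estimated correlation). These stood beside the lymph node scores above, and without the 2 arrays with those scores the calls were lost (adjusted p = 0.877, 0.813 and 0.403). When adjusted over the list alone, 11 B cell, 11 T and NK cell and 7 dendritic cell genes passed as higher, and over all genes 0, 2 and 1. In addition, 1 T and NK cell gene passed as lower over the list alone. MHC class II genes rose (median 0.66, camera adjusted p = 0.00761; adjusted p = 0.66 with an estimated correlation). Ciita was at 2.19, 3 members passed when adjusted over the list alone, and the call was lost without double knockout 1 or 3 (adjusted p up to 0.0663). Its direction turned without both of them (adjusted p = 0.478). Matrix genes fell (median -1.0, 21 of 23 negative, camera adjusted p = 1.32e-08; adjusted p = 0.446 with an estimated correlation), with 5 members past the threshold over all genes and 16 adjusted over the list alone. It was the only list that fry called in the 6 comparisons (adjusted p = 0.0224). Lox fell by 1.58, Col4a2 by 1.18 and Col5a1 by 1.53. Lipid-associated macrophage genes fell (median -1.07, 17 of 17 negative, camera adjusted p = 1.05e-05; adjusted p = 0.446 with an estimated correlation), with 4 members past the threshold over all genes and 7 adjusted over the list alone. Lgals3 fell by 2.28, Lipa by 1.51 and Atp6v0d2 by 4.02. Their score was -0.89 ± 0.28 (SD, n = 3) against 0.26 ± 0.23 (n = 3). The exact permutation p of 0.1 (0.429 adjusted over the 30 lists) is the smallest that 3 against 3 arrays allow.

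Macrophage markers fell (median -0.71, 14 of 17 negative, camera adjusted p = 0.00723; adjusted p = 0.588 with an estimated correlation). Mrc1 fell by 1.68 and Mertk fell by 1.76, while the resident macrophage gene Timd4 was at 1.34 and Adgre1 at -0.92. For this list 2 members passed over all genes and 3 adjusted over the list alone, and the call was lost without double knockout 1 (adjusted p = 0.0545). Endothelial markers fell (median -0.57, 16 of 16 negative, camera adjusted p = 0.00358; adjusted p = 0.602 with an estimated correlation), with Sox17 at -2.06. Thermogenic genes rose (median 0.56, camera adjusted p = 0.0399; adjusted p = 0.446 with an estimated correlation), with Cox8b at 2.82. Oxidative phosphorylation genes rose (median 0.14, camera adjusted p = 0.0474; adjusted p = 0.768 with an estimated correlation), with Cox4i1 past the threshold at 1.0. Skeletal muscle genes (median 2.11, camera adjusted p = 0.0474; adjusted p = 0.86 with an estimated correlation) and skin genes (median 1.36, camera adjusted p = 0.0399; adjusted p = 0.768 with an estimated correlation) rose beside them. Muscle genes scored 2.27 ± 3.02 (SD, n = 3) against 0.47 ± 1.39 (n = 3). These 4 calls were each lost without at least 3 single arrays. The thermogenic call was lost without Gipr-/- 1, double knockout 1 or 2 (adjusted p up to 0.161), and oxidative phosphorylation without WT 2 or 3, Gipr-/- 1 or 2 or double knockout 2 (adjusted p up to 0.666). Muscle was lost without WT 1, Gipr-/- 1, double knockout 1 or 2 (adjusted p up to 0.786), and skin without Gipr-/- 1 or 2 or double knockout 2 (adjusted p up to 0.852). With the title code groups as a block the direction turned for oxidative phosphorylation (adjusted p = 0.951), muscle (adjusted p = 0.0872) and skin genes (adjusted p = 0.928). Groups did not overlap for 3234 genes, 22.3% where chance gives 10%. Of the 505 genes, 0 passed without the 2 arrays with lymph node genes, a setting that leaves 1 double-knockout array assumed to vary like the other groups (2123 at an unadjusted p under 0.05), and 5 with the title code groups as a block. The count was 131 without Gipr-/- 1, 49 without Gipr-/- 2, 69 without double knockout 1, 1382 without double knockout 2, 171 without double knockout 3 and 1797 with array weights. After quantile normalization 119 genes were higher and 253 lower, and with all 22 arrays in one fit 224 were higher and 260 lower. Simulations recovered 11.4% of genes changed by 1 log2 unit and 69.6% of those changed by 2.

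Compared with WT marrow, double-knockout marrow again went with higher lymphocyte genes in ingWAT, a difference that depends on 2 arrays with lymph node genes. B cell and plasma cell genes rose (median 3.14, camera adjusted p = 3.63e-10; adjusted p = 0.686 with an estimated correlation), with Spib at 3.55. T and NK cell genes rose (median 1.96, camera adjusted p = 1.59e-07; adjusted p = 0.686 with an estimated correlation), with Ctla4 at 2.17. So did dendritic cell genes (median 1.09, camera adjusted p = 0.000177; adjusted p = 0.686 with an estimated correlation), with Fscn1 at 1.69. MHC class II genes rose as well (median 0.87, camera adjusted p = 0.000873; adjusted p = 0.834 with an estimated correlation), with H2-Ob at 3.78. In these lists 11, 11, 6 and 4 members passed when adjusted over the list alone. The lymph node stroma score was 2.00 ± 2.34 (SD, n = 3) against -0.87 ± 0.30 (n = 4) with WT marrow. Matrix genes fell (median -0.43, camera adjusted p = 0.000177; adjusted p = 0.686 with an estimated correlation). Thbs1 was at -2.04, Timp1 at -1.21 and Col1a1 at -1.10, and 4 members passed when adjusted over the list alone. Macrophage markers fell (median -0.45, camera adjusted p = 0.0283; adjusted p = 0.834 with an estimated correlation), lost without WT 2, WT 4 or double knockout 1 (adjusted p up to 0.378). Muscle genes fell (median -2.32, camera adjusted p = 0.00464; adjusted p = 0.834 with an estimated correlation), lost without WT 2, WT 3 or double knockout 3 (adjusted p up to 0.652). Limma called 0 of 14502 genes (lowest adjusted p = 0.0591; 1958 at an unadjusted p under 0.05, 1026 higher and 932 lower). The smallest p-values belonged to Cnot6l (1.74), H4c4 (1.64), the proton channel Hvcn1 (2.66), Srgn (1.89) and Eef1b2 (1.29) among higher genes. Among lower genes they belonged to the complement receptor C5ar1 (-2.42), the chaperone Cryab (-2.10), perlecan (Hspg2, -1.23), Kctd17 (-1.69) and Cyb5r3 (-1.48). Groups did not overlap for 1593 genes, 11% where chance gives 5.71%. Simulations recovered 16% of genes changed by 1 log2 unit and 77.6% of those changed by 2. The count of 0 became 620 without double knockout 2, 1 without WT 1 or WT 2, 555 with array weights, 141 with all 22 arrays, 34 with robust estimation, 15 with all features, 13 without the lower 50% of genes and 4 after quantile normalization. The 7 lists became 2, others than these, without the 2 arrays with lymph node genes. In that setting the direction turned for B cell, T and NK cell, MHC class II and muscle genes (adjusted p = 0.780 for each).

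**Figure D3:**
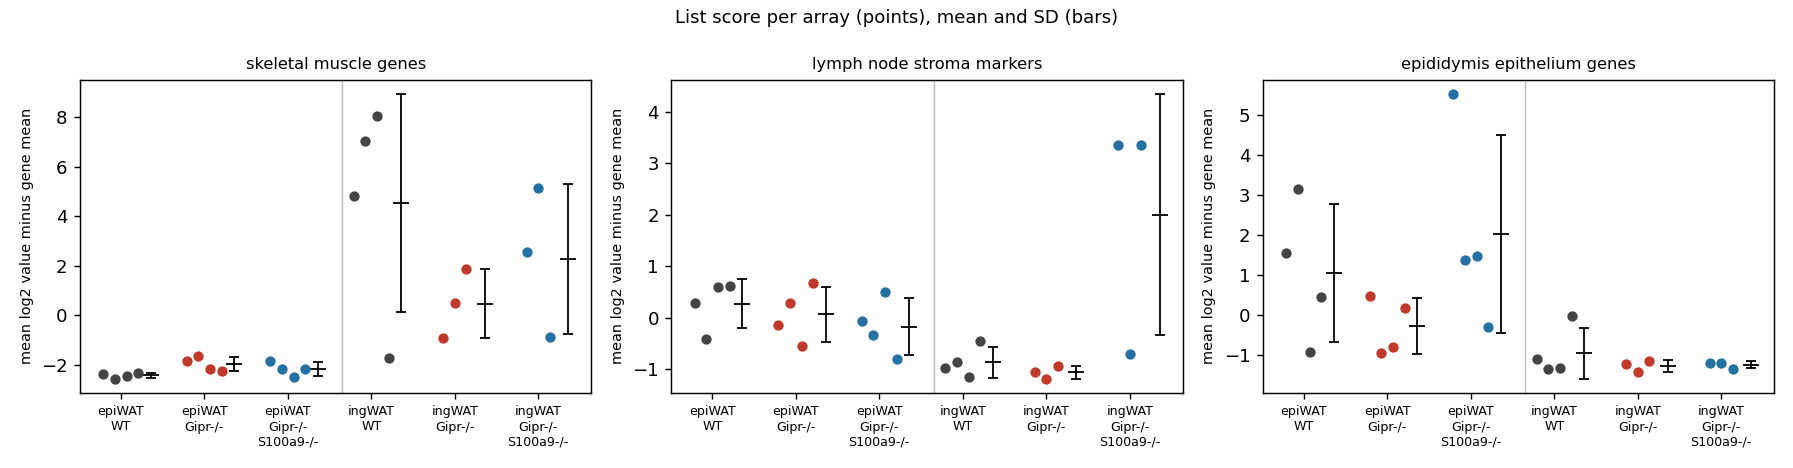
List score per array (points; y axis, mean log2 value minus the gene's mean over the 22 arrays) for genes of skeletal muscle, lymph node stroma and epididymis epithelium in the 6 groups (x axis); bars give the group mean and SD. In ingWAT muscle scores of the WT arrays run from -1.74 to 8.03 and lymph node scores of 2 double-knockout arrays reach 3.36 and 3.35; in epiWAT the highest epididymis score is 5.51.

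The effects of the comparisons that share arrays were set side by side. In epiWAT the log2 differences from WT of Gipr-/- and of double-knockout marrow correlated across genes with r = 0.183, below the 0.50 that unchanged groups sharing the WT arrays gave in simulation. The covariance was 0.0384 against 0.145 simulated. With the WT arrays split 2 and 2, r was -0.218 and the covariance -0.0796. In ingWAT r was 0.306 (simulated 0.429) and the covariance 0.117 (simulated 0.0972), and after the split r was 0.0299 and the covariance 0.0112. Genes at an unadjusted p under 0.05 in the same direction in both numbered 57 in epiWAT (168.74 simulated, 16.2 for independent lists) and 347 in ingWAT (145 simulated, 149 independent), and 0 passed the adjusted threshold in both. In opposite directions there were 8 in epiWAT (1.92 simulated, 16 independent) and 114 in ingWAT (4.1 simulated, 145 independent). The Gipr-/- against WT and double-knockout against Gipr-/- effects ran opposite. In epiWAT r was -0.761 (simulated -0.498, covariance -0.242 against -0.144), and -0.232 with a covariance of -0.100 with the Gipr-/- arrays split. There was r = -0.591 in ingWAT (simulated -0.537, covariance -0.266 against -0.130). At an unadjusted p under 0.05, 532 genes in epiWAT (168 simulated, 56.3 independent) and 1108 in ingWAT (189 simulated, 223 independent) moved in opposite directions, and 25 in ingWAT did so past the adjusted threshold in both. In ingWAT the 3 Gipr-/- arrays could not be split with 2 in each part, so part of the excess may come from the shared arrays. Genes are not independent replicates. The simulated values are means of runs in which each gene varied independently. In the epiWAT arrays 46.5% of the variance lay on a single component, so unchanged groups could lie further from these means. The gaps from the simulated values are thus no test of a marrow effect.

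With WT marrow, ingWAT and epiWAT differed in 286 genes, 149 higher and 137 lower in ingWAT (limma; 2410 at an unadjusted p under 0.05). The developmental factor Tbx15 was higher by 4.97 (SE 0.53, adjusted p = 5.11e-05), as were St6galnac5 (3.45), the chemokine Cxcl14 (3.47), Mmp3 (3.48) and Xirp1, a gene of striated muscle (1.92). The mesothelial genes Upk3b and Wt1 were lower (-6.19 and -2.42), as were Kcnj15 (-3.33), Col6a5 (-3.93) and angiotensinogen (Agt, -4.36). Inguinal depot genes rose (median 2.33, camera adjusted p = 1.18e-05, adjusted p = 0.0237 with an estimated correlation), with 3 of 5 past the threshold, among them Shox2 (2.33) and Hoxc10 (3.15). Hoxc9 was at 0.71 and did not pass, and Sfrp2 went the other way at -1.58 without passing (limma adjusted p = 0.279). Epididymal depot genes (median -0.76, camera adjusted p = 8.09e-05; adjusted p = 0.0117 with an estimated correlation) fell and had 2 of 7 past the threshold, Wt1 and Tcf21 (-2.92), and mesothelium markers (median -2.88, camera adjusted p = 4.98e-13; adjusted p = 0.0119 with an estimated correlation) 7 of 11. The thermogenic list rose (median 1.39, camera adjusted p = 1.58e-06; adjusted p = 0.0127 with an estimated correlation), with skeletal muscle genes beside it (median 6.81, 14 of 18 past the threshold, camera adjusted p = 9.31e-25; adjusted p = 0.0534 with an estimated correlation). Camera also called macrophage markers (median -0.77) and lipogenesis (-0.34) as lower and oxidative phosphorylation (0.24), fatty acid oxidation (0.36), mast cell markers (0.63) and skin genes (1.96) as higher in ingWAT. These lost their calls with an estimated correlation (lowest adjusted p = 0.263 with an estimated correlation). The count of 286 was 150, 138 and 81 without ingWAT WT 1, 2 and 3, and 104, 110, 91 and 136 without epiWAT WT 1, 2, 3 and 4. It was 154 without the lower 50% of genes and 791 with array weights. It was also higher without 6 arrays, the 2 with lymph node genes and the 4 epiWAT arrays with a positive first component.

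Whether a marrow effect differed between the depots was tested directly. For double-knockout against Gipr-/- marrow 104 genes differed, 50 with a higher and 54 with a lower difference in ingWAT than in epiWAT (limma; 2000 at an unadjusted p under 0.05). The histone genes H4c12 (2.42, SE 0.38, adjusted p = 0.0114) and H4c3 (2.45) and the glycosylation genes B3gnt5 (4.35) and St8sia1 (2.7) and Ints13 (1.99) led the first group. Surf4 (-1.77, SE 0.24, adjusted p = 0.00362), the transporter Slc16a12 (-3.27), Fbxl4 (-1.87), Gpc4 (-2.47) and the ceramide synthase Cers4 (-2.84) led the second. In ingWAT with double-knockout marrow the SD (n = 3) was 1.77 for B3gnt5, 0.91 for St8sia1 and 0.83 for H4c3. It was 0.28 for H4c12 and 0.21 for Ints13. That group holds the 2 arrays with lymph node genes, and whether they carry these differences was not tested. Lists that differed were B cell (3.62), T and NK cell (1.73), dendritic cell (1.23), MHC class II (1.83), cell cycle (0.49), thermogenic (0.50) and skeletal muscle genes (2.19) with higher medians in ingWAT and lipogenesis (-0.56), endothelial (-0.78) and epididymis genes (-3.60) with lower ones. Each list lost its call with an estimated correlation (lowest adjusted p = 0.513 with an estimated correlation). Lymph node stroma genes moved with the immune lists, at 2.00 ± 2.34 (SD, n = 3) in ingWAT with double-knockout and -1.06 ± 0.13 (n = 3) with Gipr-/- marrow. The count of 104 was 26, 5, 7, 543 and 21 without ingWAT Gipr-/- 1, Gipr-/- 2, double knockout 1, double knockout 2 and double knockout 3. It was 29, 35, 259, 47, 58 and 51 without epiWAT Gipr-/- 1, Gipr-/- 4, double knockout 1, double knockout 2, double knockout 3 and double knockout 4. It was 69 without the filter and 927 with array weights. It was lower without 6 arrays, the 2 with lymph node genes and the 4 epiWAT arrays with a positive first component. That setting leaves a single ingWAT double-knockout array. For Gipr-/- against WT marrow limma called 0 genes (lowest adjusted p = 0.053, 1153 at an unadjusted p under 0.05), led by Slc16a12 (2.88) and Cpq (1.56). The count was 1 without ingWAT double knockout 2, 2 without epiWAT Gipr-/- 4, 2 without the lower 50% of genes and 28 with array weights. Lists that differed here were muscle (-4.91), skin (-2.09), thermogenic (-0.71), B cell (-0.72), lipid-associated macrophage (-0.42) and cell cycle genes (-0.31) with lower and lipogenesis (0.86), endothelial (0.79) and interferon genes (0.64) with higher medians in ingWAT. Each lost its call with an estimated correlation (lowest adjusted p = 0.591 with an estimated correlation).

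Some lists were called in none of the 6 comparisons within a depot. These were neutrophil markers (medians from -0.17 to 0.06, lowest adjusted p = 0.46), monocyte markers (-0.55 to 0.29, 0.064) and the S100 family and alarmin receptors (-0.28 to 0.08, 0.102). Others were inflammatory cytokines and chemokines (-0.55 to 0.26, 0.196), type 2 immunity (-0.29 to 0.15, 0.328), mast cell (-0.30 to 0.11, 0.34) and adipose progenitor markers (-0.21 to 0.43, 0.122) and circadian clock genes (-0.28 to 0.07, 0.359). In some comparisons the median, mean and camera direction of these small shifts differed in sign, as for neutrophil markers in epiWAT with double-knockout against WT marrow (median -0.17, mean 0.05, direction down) and monocyte markers in ingWAT with double-knockout against Gipr-/- marrow (median -0.37, mean 0.04, direction down). The cytokine gene Il1b differed by between -0.87 and 0.52 and Il10 by between 0.09 and 0.42, with no adjusted p under the threshold. Red blood cell genes, with 4 in the table, were not tested.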

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

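The counts of other splits of the samples were planned; the tests that weigh explanations in this part, on covariates, list members, array scores and the title code block, were all chosen after the results were seen.

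Some arrays stood apart from the 3 others of their group, on 204 combinations of group and measure tested; about 1 in 20 stands out by chance, and 13 did. In epiWAT with Gipr-/- marrow, array 1 was low for interferon response genes (-1.41, others -0.10 to 0.00) and for Prdm16, a regulator of brown and beige fat (3.95, others 4.64 to 4.78). Array 3 was high for immediate early genes (0.87, others -0.11 to 0.04) and array 4 for Ucp1, the uncoupling protein of thermogenic fat (8.45, others 3.45 to 4.28). With double-knockout marrow, array 4 was high for oxidative phosphorylation genes (0.39, others -0.34 to -0.23), array 3 for Ppargc1a (9.62, others 7.79 to 7.91) and array 2 for the monocyte gene Ly6c2 (9.25, others 7.99 to 8.13). With WT marrow, array 2 was low for immediate early genes (-0.61, others -0.20 to -0.19), Ucp1 (3.23, others 3.68 to 3.73) and Ly6c2 (7.68, others 9.12 to 9.39). In ingWAT with WT marrow, array 2 was high for cell cycle genes (0.36, others -0.32 to -0.25) and Il6 (4.41, others 3.37 to 3.47), and array 4 for red blood cell genes (1.39, others 0.03 to 0.21). The effect of double-knockout against Gipr-/- marrow differed between the depots for 104 genes, by the test of the difference itself.

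Other splits of the arrays were set beside each count, and each number of splits given includes the real one. In epiWAT 2 of 35 splits gave as many genes at an unadjusted p under 0.05 as Gipr-/- against WT marrow (1052, highest other 1245), 7 of 35 as double knockout against Gipr-/- (1555, highest other 3349) and 15 of 35 as double knockout against WT (444, highest other 3448), so chance is not excluded for these. For double knockout against WT, splits with several times the real count point to a structure of the epiWAT samples other than the marrow. In ingWAT 2 of 35 splits gave as many genes past the adjusted threshold as Gipr-/- against WT (34, highest other 59), and chance is not excluded. For double knockout against Gipr-/- in ingWAT the 10 splits are too few for a share under 0.05 (505, highest other 0; 1 split, the real one, as large). For double knockout against WT in ingWAT only the real split, 1 of 35, gave as many genes at an unadjusted p under 0.05 (1958, highest other 1871). This is the smallest share that 35 splits allow, the next count is close, and the shares were not corrected over the comparisons. Chance is therefore not excluded here. Between depots, no other split gave as many as the 104 genes (1 of 100 splits, highest other 42). The same held for the 286 genes that differ with WT marrow (1 of 35, highest other 1). Both are the smallest shares these splits allow, and the shares were not corrected over the comparisons. The 286 genes stand far above the highest other count of 1, which argues against chance for them. The count of 104 fell to 5 without ingWAT Gipr-/- 2. The shuffles behind it also move the 2 arrays with lymph node genes out of their group. Chance is therefore not excluded for the 104 genes, and their count is not tied to the marrow by these splits. Chance is not excluded for Gipr-/- against WT (15 of 100 splits, 1153 genes, highest other 3097).

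The first pattern is the difference between double-knockout and Gipr-/- marrow in ingWAT. For the 384 lower genes dilution of fat by lymph node as the main cause is argued against. The mature adipocyte genes had a median difference of -0.0258 (SD 0.848 over 17 genes) where the lower genes had -1.59. The lower genes were chosen for being lower, so a smaller part by dilution is not excluded. For the 32 T, NK and B cell genes a candidate explanation is lymph node tissue in arrays 1 and 3. Their median difference was 0.0789 in array 2 against 3.51 and 3.91 in arrays 1 and 3. With the lymph node score as a covariate it went from 2.41 to -0.438 (SD 0.576 over the genes). That score is high only in arrays 1 and 3, so the adjusted value also rests on array 2 and is no separate support. The stroma gene Ccl21a averaged 12.43 ± 4.16 (SD, n = 3) against 6.69 ± 0.54 (n = 3). For the 121 higher genes lymph node tissue and the marrow cannot be told apart, since their median of 1.24 with the covariate (SD 0.582) beside 1.62 without (SD 0.843) rests on array 2 alone, while their median SE rose from 0.314 to 0.431. Array 2, with a low lymph node score, still had a median of 1.28 beside 1.81 and 1.66 in arrays 1 and 3, but the genes were chosen from a fit that includes it, and it holds the highest hair follicle score (8.62, against -0.97 and -0.45 in arrays 1 and 3). The title code groups partly follow this comparison: Gipr-/- arrays had codes 91, 92 and 71, and double-knockout arrays 73, 74 and 75. With these groups as a block most of the 505 calls were lost, as given above. The code groups thus cannot be fully told apart from the marrow for the lower and the higher genes. The loss of S100a9 from the marrow stays open for both.

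The second pattern is the lower expression of lipid-associated macrophage genes in epiWAT with double-knockout than with Gipr-/- marrow. With the epididymis score as a covariate the list's median was -0.997 (SD 1.58 over 17 genes) where it was -1.51 (SD 1.40) without. Epididymis tissue in some arrays may thus account for part of the difference, and it cannot be told apart from the marrow here. The SD is the spread between genes and does not measure the uncertainty between arrays. The list's camera call held in 15 of 18 settings. The call was lost only with the estimated correlation, fry and the permutation, which no list could pass alone. It thus held without the epiWAT arrays with a positive first component, and without any single array (highest camera adjusted p = 2.16e-08). This argues against epididymis tissue in those arrays as the only source of the call. Fewer macrophages of every kind may also lower the list: the list score minus the general macrophage score differed by -0.877, but the arrays overlapped, with the highest double-knockout array at 0.536 and the lowest Gipr-/- array at 0.322, so this cannot be told apart from a change within macrophages. The loss of S100a9 from the marrow stays open.

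The third pattern is the lower expression of thermogenic genes in ingWAT with Gipr-/- than with WT marrow. Skeletal muscle in the WT arrays may account for it: the 9 members not known from muscle had a median of -0.211 where those that muscle shares had -1.90. Members that go both ways keep this open, and it cannot be told apart from a change in the adipocytes. With the title code groups as a block the median was -0.635 where it was -0.849 without, which leaves the meaning of the codes open as well. The kind of marrow stays among the open explanations.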

How the results depend on the processing

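Fits without arrays rich in lymph node genes or with a positive first component in epiWAT were chosen after the data were seen. So were fits with tissue scores as covariates, the exact permutation of list scores and the code block for lists. The other settings were planned. Within a depot no pairs were used, because the array numbers follow the accession order and pair nothing. Between depots, with samples whose title codes differ by 15 as a random block, 0 genes (Gipr-/- against WT; 1162 at an unadjusted p under 0.05), 107 (double knockout against Gipr-/-) and 309 (WT depots) passed in limma. Where a result differed, the cause was not tested, except that fewer arrays or genes are part of some settings. Without the 2 lymph node arrays (double knockout 1 and 3) a lone double-knockout sample is assumed to vary like the other groups. The 4 epiWAT arrays left out are WT 2, Gipr-/- 1 and double knockout 1 and 3, and the 6 arrays are these and the 2 with lymph node genes.

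Counts of genes, by setting. EpiWAT Gipr-/- against WT (0): array weights 26, all features 6, epididymis covariate 16, leave-one-out 0 to 1. EpiWAT double knockout against Gipr-/- (0): all 22 arrays 1. IngWAT Gipr-/- against WT (34): lower 50% left out 148, no trend 1, robust 133, array weights 401, quantile 3, all 22 arrays 99, code block 0 (1724 at an unadjusted p under 0.05 in limma), without lymph node arrays 86 (34 shared), lymph node and muscle covariates 0 (1832), leave-one-out 0 to 274. IngWAT double knockout against Gipr-/- (505): array weights 1797, code block 5, without lymph node arrays 0 (2123), covariates 0 (1935), leave-one-out 49 to 1382. IngWAT double knockout against WT (0): lower 50% left out 13, robust 34, array weights 555, quantile 4, all features 15, all 22 arrays 141, leave-one-out 0 to 620. Between depots, Gipr-/- against WT (0): lower 50% left out 2, array weights 28, leave-one-out 0 to 2; double knockout against Gipr-/- (104): no filter 69, array weights 927, without 6 arrays 32, leave-one-out 5 to 543; WT depots (286): lower 50% left out 154, array weights 791, without 6 arrays 480, leave-one-out 81 to 373.

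Counts of lists were 0 in all 6 comparisons with an estimated correlation and with the exact permutation, and 0 with fry except 1 in ingWAT double knockout against Gipr-/-. In that comparison no list could pass the permutation, since 3 against 3 arrays allow too few splits. In the other comparisons the smallest exact p possible was 0.0286, which passes adjustment only if many lists reach it together. Their counts of 0 with the permutation thus say little about any single list. For epiWAT double knockout against WT (9) they were 3 after quantile normalization, 1 without the 4 arrays and 1 to 10 leaving out 1 array; for ingWAT Gipr-/- against WT (7) 4 to 10; for ingWAT double knockout against Gipr-/- (12) 6 without the lymph node arrays and 8 to 13; for ingWAT double knockout against WT (7) 2 without the lymph node arrays and 6 to 9; for the other epiWAT comparisons 8 to 15 and 7 to 10. The lipid-associated macrophage call held in 15 of 18 settings for Gipr-/- against WT (highest adjusted p leaving out 1 array 3.73e-07) and in 15 of 18 for double knockout against Gipr-/- in epiWAT (2.16e-08), and in 14 of 17 for each of these in ingWAT (0.0232 and 0.000953); the settings without the call include the estimated correlation, fry and the permutation. Camera's direction turned in 1 setting each for 11 called lists: 3 in epiWAT double knockout against WT, 4 in ingWAT double knockout against Gipr-/- and 4 in ingWAT double knockout against WT. At an unadjusted p the overlap of the effects against WT was 57 genes in epiWAT and 347 in ingWAT, where it was 0; with the WT arrays split, the correlation was -0.218 in epiWAT and 0.0299 in ingWAT.

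Of the settings of named genes, 5513 kept direction and side of the threshold, 204 passed it newly, 426 no longer passed and 59 reversed. EpiWAT Gipr-/- against WT: S100a9 (-0.19) 0.17 with array weights, 0.0274 without the 4 arrays, -0.38 to 0.0181 leaving out 1 array. EpiWAT double knockout against Gipr-/-: Gipr (-0.49) 0.26 without the 4 arrays; S100a9 (0.00) -0.34 with array weights, -0.0883 without the 4 arrays, -0.0919 with the covariate, -0.20 to 0.19 leaving out 1; Rnase9 (4.36) -0.26 with the covariate. EpiWAT double knockout against WT: Gipr (0.10) -0.31 to 0.39 leaving out 1; S100a8 (-0.16) 0.26 with array weights, 0.14 without the 4 arrays, 0.0675 with the covariate, -0.60 to 0.35 leaving out 1; without the 4 arrays Crat (-0.56) 0.13, Plin2 (-0.80) 0.15, Cldn4 (0.70) -0.37 and Defb20 (0.75) -0.48, the last -0.44 to 1.40 leaving out 1. IngWAT Gipr-/- against WT: Gipr (0.09) -0.19 to 0.31 leaving out 1; S100a8 (0.30) -0.0832 with the code block, -0.16 to 0.95 leaving out 1. IngWAT double knockout against Gipr-/-: without the lymph node arrays Gipr (0.31) -0.19, S100a9 (-0.34) 0.0202, Ndufa8 (-0.93) 0.0349, H2-DMb2 (2.54) -1.62; with the covariates Gipr -0.36, Cd3g (4.29) -0.0224, Ppargc1a (1.46) -0.47, Ndufa8 0.12, Cd8a (4.73) -1.06, Pax5 (3.64) -0.49, Spib (3.0) -0.16, H2-DMb2 -2.09, Eno3 (2.27) -0.47, Myh4 (3.99) -0.0169; with the code block Actn3 (2.47) -0.42, Eno3 -0.93, Myh4 -2.52, Pvalb (3.05) -1.61; S100a9 -0.75 to 0.10 leaving out 1. IngWAT double knockout against WT: without the lymph node arrays Gipr (0.40) -0.10, Ccl22 (3.95) -1.12, H2-DMb2 (3.44) -0.73; with the covariates Gipr -0.0865, Ccl22 -1.40, Ciita (1.70) -0.00859, H2-DMb2 -1.01; S100a9 (0.17) -0.092 to 0.61 leaving out 1. Arrays have no read depth; Gipr, S100a8 and S100a9 lie low in signal, and some of their differences change sign with the setting, as given above.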

Other observations

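The gene lists of testis, hair follicle and liver in this part, and the tests of likeness between depots and of title codes, were all chosen after the data were seen.

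Genes of other tissues stood out in single arrays. The first component of the epiWAT arrays held 46.5% of the variance, with positive values in WT 2 (78.4), Gipr-/- 1 (74), double knockout 1 (113) and double knockout 3 (53.4), and was led by the epididymal secretory genes Serpina16, Wfdc15b, Wfdc16, Defb39 and Defb22. The score of 18 testis germ cell genes was 6.74 in epiWAT Gipr-/- 1 and 3.02 in epiWAT WT 2, where the other epiWAT arrays had -0.99 to 1.62 and the ingWAT arrays -1.32 to -0.47. The score of 17 hair follicle genes was 7.96 in ingWAT WT 2, 8.62 in ingWAT double knockout 2 and 2.58 in ingWAT Gipr-/- 3, where the other ingWAT arrays had -0.98 to 0.38 and the epiWAT arrays -1.36 to -1.08. The score of 16 liver secretory genes ran from -2.57 (epiWAT double knockout 1) to 2.69 (epiWAT WT 1), with no array apart from the others.

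The effects of double-knockout against Gipr-/- marrow may be alike in the depots. Across 13872 genes they correlated with r = 0.106, and 14 of 100 arrangements of the labels gave as high an r (highest 0.212), so chance is not excluded. Samples of the depots whose title codes differ by 15 may come from 1 mouse: the mean correlation of their deviations from the group was 0.0155 over 7 pairs (-0.0719 to 0.0741), and 511 of 2304 pairings gave as high a mean, which leaves this open.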
